A study of Rattus norvegicus with 12 samples.

How the data were processed

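RNA was measured in bone taken from around mini-implants placed at the maxillary first molar site of wild-type rats. Per the labels, the implants were titanium (cpTi) or the alloy Zr58Cu25Al14Nb3 (called Nb3 alloy here), and they were either loaded cyclically for 2 weeks or left static. Bone within a diameter of 4 mm was collected. The 12 libraries fall into 4 groups of 3: loaded Nb3 alloy, non-loaded Nb3 alloy, loaded cpTi and non-loaded cpTi. RNA was isolated with TRIzol, and libraries of polyadenylated RNA were made with a NEBNext Ultra kit, per the labels' protocols. Nothing in the labels says that the replicates of a group are separate animals, so every p-value measures only the spread between these samples.

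The authors deposited 1 table of FPKM (fragments per kilobase, scaled by depth) for 33801 genes, with gene length and position. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, without saying which step each one did. The genome build, annotation release and strand setting are not given in the sources used here, so positions are printed as the deposited table gives them. No symbol is given for 3241 genes, and 236 symbols stand on more than 1 gene. Within each library the deposited FPKM multiplied by gene length came in whole steps of 1 read, for 100% of values within 0.01 read. That gave the reads on genes behind each library, 12911912 to 22308428 (12.9 to 22.3 M). The depth by which the deposited FPKM was scaled was not the library total. It followed a median-of-ratios size factor recomputed from the reads, with a ratio of 0.995 to 1.02 in the 12 libraries.

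A gene was tested where it reached 1 FPKM in at least 3 libraries, which 15268 genes did and 18533 did not. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 libraries in the fit, 8 residual degrees of freedom, and trended and robust empirical Bayes moderation. A fold change is therefore on the log2(FPKM + 1) scale and understates the change of genes with low values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 7 comparisons were the loading effect in each material, the material effect in each loading state, the interaction of both, and the averaged effects of loading and of material. The design foresaw a count model had the file held counts. Because it held FPKM, the fallback set out in the design was followed, and edgeR and DESeq2 were not used here. Reads recovered from the FPKM steps served only limma-voom and other alternatives, tests and descriptions.

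Before the data were examined, the comparisons, thresholds, 40 gene lists, alternatives and the rule for naming genes were fixed. The rule takes, in each simple comparison, the 8 genes that rose and the 8 that fell most among called genes with a symbol that is not a placeholder (such as LOC with a number), a mean of at least 1 FPKM and no overlap between the libraries of the groups (5 and 5 in the interaction and averaged comparisons). It adds up to 4 called members of each list by smallest p and a panel of 12 bone genes. Where no gene qualified, the 3 with the smallest p are given as values. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 40 lists, and each had at least 5 tested members. The alternatives were a correlation estimated per list and the rotation test fry, which asks whether the genes of a list move one way on balance. Lists share some members (Postn, for example, is in the osteoblast and the ligament list), so their results are not independent.

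Alternatives fixed in advance were recomputed size factors, no filter, a filter of 1 CPM in 6 libraries, a replicate block, a non-robust fit, a pseudocount of 0.1, limma-voom on the whole reads, thresholds with an absolute log2 fold change of at least 1, a fit of the compared groups alone, and each library left out in turn. Scaling by total reads, scaling by nuclear reads and quantile normalization were added after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 served limma.

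The procedure was tested on simulated data for 15268 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For the loading effect in Nb3 alloy it recovered 53% and 87% of them, with 6.67% false calls. For the loading effect in cpTi the shares were 39% and 88% (2.31% false), for the material effect under loading 58% and 84% (4.70%), and for the material effect without loading 52% and 85% (6.80%). For the interaction they were 15% and 75% (6.25%), for averaged loading 74% and 94% (3.45%), and for averaged material 77% and 92% (5.06%). In a simulation of the loading effect in Nb3 alloy, the list test called the 1 list that had been moved and 0 of the others. In all these simulations genes were drawn independently of each other, and the changed genes had many reads. The simulations therefore do not show how the tests behave with correlated genes or with low genes. Few genes were changed and the size factors were known, so errors of scaling when many genes move were not simulated either. In the averaged comparisons the genes were changed alike in both groups of one side, not in 1 group alone. Genes with near-identical copies, such as the defensin genes Defa5, Np4 and RatNP-3b, share sequence, and how reads were divided among them is uncertain.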

Results

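Expression was measured in 12 libraries of bone from around rat mini-implants, 3 each for loaded Nb3 alloy, non-loaded Nb3 alloy, loaded cpTi and non-loaded cpTi. The series asks how cyclic loading changes gene expression beside an implant of each material. Reads on genes averaged 18.8 ± 3.08 M in loaded Nb3 alloy (SD, n = 3), 14.7 ± 0.643 M in non-loaded Nb3 alloy, 14.9 ± 0.952 M in loaded cpTi and 14.0 ± 1.03 M in non-loaded cpTi. The 3 loaded Nb3-alloy libraries stood apart from the other 9. They correlated with the others at 0.731 to 0.866 across the 15268 tested genes, while the other 9 correlated with each other at 0.932 to 0.969. Reads on mitochondrial genes made up 11.97%, 24.3% and 11.3% of the loaded Nb3-alloy libraries (replicates 1, 2 and 3) and 4.31% to 6.86% of the others. Replicate 2 of this group also had the most reads (22.3 M) and the fewest genes with exactly 1 read (224, against 595 to 1267 in the others).

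**Figure D1:**
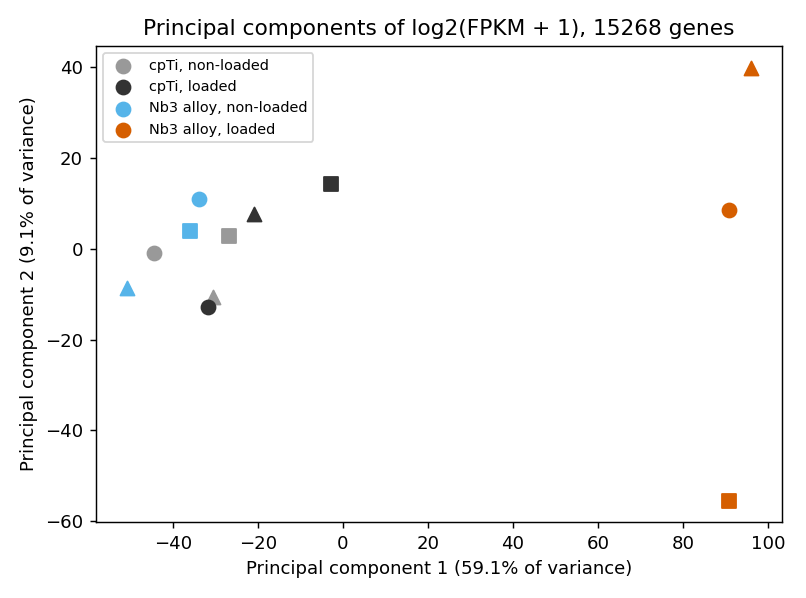
Principal components 1 (59.1% of variance) and 2 (9.08%) of log2(FPKM + 1) over 15268 genes, 1 point per library, coloured by group, with circles, squares and triangles for replicates 1, 2 and 3. The 3 loaded Nb3-alloy libraries lie at the right, apart from the other 9.

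Loading beside the Nb3 alloy came with a near loss of blood-forming transcripts. Mpo (ENSRNOG00000008310, chromosome 10, 72594661 to 72604819), the myeloperoxidase of neutrophil granules, stood at 0.328 ± 0.169 FPKM in loaded and 738 ± 329 FPKM in non-loaded samples (SD, n = 3 each). It fell by 9.04 on the log2 scale (SE 0.27, adjusted p = 1.53e-08). Slc4a1, the anion exchanger of red cells, went from 711 ± 235 to 5.19 ± 3.61 FPKM, and Mki67, a marker of dividing cells, from 126 ± 26.2 to 2.81 ± 0.697 FPKM. The gene that rose most was Slpi (ENSRNOG00000046699, chromosome 3, 153082369 to 153084453), an inhibitor of neutrophil proteases, at 8354 ± 2446 FPKM in loaded and 41.3 ± 10.2 FPKM in non-loaded samples (log2 difference 7.61, SE 0.94, adjusted p = 0.000108).

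The fall covered every marrow lineage among the lists except monocytes and T cells. Of 25 neutrophil and granule genes 22 fell (24 adjusted over the list alone), with a median log2 difference of -5.27. Among them were Elane (-8.03), Ctsg (-7.53) and Prtn3 (-5.95), proteases of the granules made by precursors, and the defensin genes RatNP-3b (-8.89), Defa5 (-8.77) and Np4 (-8.62), which share sequence and cannot be separated with certainty. The list was lower by camera (adjusted p = 4.51e-12, adjusted p = 0.265 with an estimated correlation). All 21 erythroid genes fell (21 adjusted over the list alone), among them Car1, a carbonic anhydrase of red cells (-7.55), Hemgn (-6.36), the ammonium channel subunit Rhag (-5.84) and the red cell transcription factor Klf1 (-5.73). Their median was -5.26 (adjusted p = 6.9e-17, adjusted p = 0.265 with an estimated correlation). All 28 cell cycle genes fell (28 adjusted over the list alone), with Ccnb2 at -4.66, Top2a at -4.34 and Plk1 at -4.10, and a median of -3.36 (adjusted p = 5.62e-21, adjusted p = 0.265 with an estimated correlation). Of 12 megakaryocyte and platelet genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), including the platelet receptor genes Gp9 (-3.94) and Itga2b (-3.52), with adjusted p = 3.69e-05 and adjusted p = 0.281 with an estimated correlation. Of 23 B lineage genes 18 fell and 2 rose (18 and 3 adjusted over the list alone). The recombinase gene Rag1 (-3.90) and the B cell factor Pax5 (-3.83) fell, while the plasma cell surface gene Sdc1, which epithelia also express, rose (2.91). The list had adjusted p = 7.36e-05, and adjusted p = 0.34 with an estimated correlation. Of 11 mast cell genes 10 fell (11 adjusted over the list alone), led by the protease gene Mcpt9 (-4.92), with adjusted p = 4.77e-05 and adjusted p = 0.269 with an estimated correlation. The same 3 libraries held 15.8 ± 7.30% mitochondrial reads, against 4.64 ± 0.508% in the non-loaded ones.

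Matrix genes and markers of vessel, smooth muscle and nerve rose in the same comparison. Of 27 collagen and matrix assembly genes 26 rose (26 adjusted over the list alone), with a median of 2.11 (adjusted p = 7.3e-12, adjusted p = 0.265 with an estimated correlation). Fmod, a collagen-binding proteoglycan, went from 2.22 ± 0.388 to 57.2 ± 18.0 FPKM, the elastin gene Eln from 1.803 ± 0.735 to 22.4 ± 2.44 FPKM, and Lum from 104 ± 22.2 to 558 ± 78.9 FPKM. Thbs2 and Matn4, which encode proteins of the extracellular matrix, rose by 5.62 (SE 0.82) and 6.96 (SE 1.22). Of 16 smooth muscle and pericyte genes 15 rose (16 adjusted over the list alone), among them Tagln (3.53) and Acta2 (3.13), with a median of 1.92, adjusted p = 9.58e-08 and adjusted p = 0.265 with an estimated correlation. All 16 Schwann cell and nerve genes rose (16 adjusted over the list alone), including the glial factor Sox10 (2.77) and S100b (1.89), with adjusted p = 1.31e-06 and adjusted p = 0.265 with an estimated correlation. Of 21 endothelial genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), with the apelin receptor gene Aplnr at 3.12 and Pecam1 at 2.05 (adjusted p = 1.12e-06, adjusted p = 0.265 with an estimated correlation). Of 10 ligament and tendon genes 8 rose (8 adjusted over the list alone), including Tnmd, from 0.154 ± 0.0885 to 12.7 ± 1.63 FPKM (adjusted p = 0.000492, adjusted p = 0.265 with an estimated correlation). Of 20 matrix breakdown genes 13 rose and 1 fell (14 and 1 adjusted over the list alone). Mmp2, a gelatinase, rose by 3.44, and Mmp8, the collagenase of neutrophils, fell by 5.51 (adjusted p = 0.000159, adjusted p = 0.265 with an estimated correlation).

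Bone-cell genes differed between the loaded libraries. Relative to the mean of non-loaded Nb3 alloy, the osteoblast list had a median of 1.65, -0.13 and 1.75 in loaded replicates 1, 2 and 3. The osteocyte list had 0.83, -0.55 and 0.75 in the same order. Of 23 osteoblast and bone matrix genes 8 rose and 0 fell by limma (7 and 0 adjusted over the list alone), with a median of 1.03 (adjusted p = 0.00048, adjusted p = 0.467 with an estimated correlation). Postn rose from 33.1 ± 4.91 to 785 ± 272 FPKM, Sparc from 721 ± 244 to 3163 ± 527 FPKM and the type I collagen gene Col1a1 from 2224 ± 1432 to 7323 ± 2377 FPKM. Of the 12 panel genes, Col1a1 (1.84, adjusted p = 0.00409), the matrix protein gene Spp1 (1.33, adjusted p = 0.0171), the osteoclast protease gene Ctsk (1.81, adjusted p = 0.0223) and Tnfsf11, which encodes RANKL (1.79, adjusted p = 0.00293), rose. The call of Ctsk was lost without loaded replicate 1 (1.40), without loaded replicate 3 (1.62), without non-loaded replicate 1 (1.59) and without non-loaded replicate 3 (1.71), and by total-read scaling (1.63). The call of Spp1 was lost without loaded replicate 3 (1.10) and without non-loaded replicate 2 (1.04), and quantile normalization ended those of Spp1 (0.97) and Col1a1 (0.82). Not called were Alpl (1.44, adjusted p = 0.0513), Acp5 (1.28, adjusted p = 0.151), Bglap (0.82, adjusted p = 0.291), Runx2 (0.70, adjusted p = 0.0965), Sp7 (0.69, adjusted p = 0.275), Dmp1 (0.65, adjusted p = 0.319), Tnfrsf11b (0.48, adjusted p = 0.395) and Sost (-0.47, adjusted p = 0.633). Loaded replicate 2 held these values down. Without it Alpl (2.23), Acp5 (2.11), Bglap (1.65), Sp7 (1.37), Dmp1 (1.28) and Runx2 (1.09) were called higher, Sost stood at 0.24, and the median of the osteoblast list was 1.65. Without loaded replicate 3 that median was 0.65. Alpl was also called with the filter on CPM (1.44) and by limma-voom (1.46). The osteocyte list had 1 of 14 genes higher, Pdpn at 1.74 (1 adjusted over the list alone), and was not called (median 0.44, adjusted p = 0.146), but it was without loaded replicate 2 (adjusted p = 0.0117) and without non-loaded replicate 1 (adjusted p = 0.0406). The osteoclast list had 7 higher and 3 lower of 18 (11 and 3 adjusted over the list alone) and was not called (median 0.61, adjusted p = 0.0777), but it was without loaded replicate 2 (adjusted p = 0.0113). Among its lower members were Traf6 (-1.03) and the carbonic anhydrase gene Car2 (-4.15), which red cells also express. Of 10 genes of the RANKL and OPG axis 7 rose (7 adjusted over the list alone), with Efnb2 at 2.02 and Ephb4 at 1.47 (adjusted p = 0.00194, adjusted p = 0.265 with an estimated correlation).

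Genes of mechanical and growth signalling rose in part. In the same comparison 116 pooled marker genes of non-marrow cell types had a median of 1.197. A change in these pathways was therefore not told apart from a lower share of marrow cells. Of 23 mechanosensing and early load response genes 13 rose (14 adjusted over the list alone), including the channel gene Trpv4 (2.12), endothelial nitric oxide synthase Nos3 (2.85), Timp1 (3.47) and Jun (1.42), with adjusted p = 0.000127 and adjusted p = 0.265 with an estimated correlation. Of 25 Wnt genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with Wnt4 at 1.94 and Wnt5a at 1.65 (adjusted p = 0.00194, adjusted p = 0.281 with an estimated correlation). Of 31 BMP and TGF-beta genes 14 rose (14 adjusted over the list alone), with Ltbp2 at 2.15 and Id1 at 1.40 (adjusted p = 0.000552, adjusted p = 0.34 with an estimated correlation). Of 20 YAP and TAZ targets 9 rose and 3 fell (10 and 3 adjusted over the list alone), with Ccn2 at 1.98 (adjusted p = 0.0113, adjusted p = 0.34 with an estimated correlation).

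Inflammatory genes rose while granule genes fell. Of 22 cytokine and chemokine genes 16 rose and 0 fell by limma (16 and 0 adjusted over the list alone), with a median of 2.06 (adjusted p = 1.23e-05, adjusted p = 0.34 with an estimated correlation). Cxcl6, a chemokine that draws neutrophils, went from 0.453 ± 0.00674 to 58.8 ± 53.4 FPKM, Ccl2, which draws monocytes, from 1.83 ± 0.734 to 31.2 ± 19.1 FPKM, and Il1b from 9.18 ± 3.27 to 94.7 ± 96.2 FPKM. The B cell chemokine gene Cxcl13 rose by 5.93 (SE 0.89), the arginase gene Arg1 by 5.03 (SE 0.57) and Acod1, which makes itaconate in activated macrophages, by 4.67 (SE 0.62). Fdcsp, a peptide gene of follicular dendritic cells and the junctional epithelium, stood at 138 ± 167 FPKM in loaded and 0.0641 ± 0.111 FPKM in non-loaded samples. Arg1 stood at 56.4 ± 62.4 FPKM and Acod1 at 44.0 ± 53.0 FPKM in loaded samples. The SD of Il1b, Arg1, Acod1 and Fdcsp in loaded samples exceeded their means, so the 3 libraries differed widely, and by limma-voom Fdcsp (8.18) and Cxcl6 (6.12) were not called. Of 21 monocyte and macrophage genes 7 rose and 3 fell (7 and 3 adjusted over the list alone). Apoe (3.92) and the lipid receptor gene Trem2 (2.03) rose and Cd163, a scavenger receptor of resident macrophages, fell (-2.31). That list was not called (adjusted p = 0.177), but it was without loaded replicate 3 (adjusted p = 0.0198).

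Copper makes up part of the alloy, so genes of metal handling were examined as a list. Of 18 such genes 6 rose and 3 fell (7 and 3 adjusted over the list alone) and the list was not called (median 0.25, adjusted p = 0.352). The metallothionein gene Mt2A rose from 27.7 ± 9.29 to 92.2 ± 36.9 FPKM and the ceruloplasmin gene Cp by 1.04. The copper exporter gene Atp7b fell by 2.79 and Slc30a10, a manganese exporter gene, by 2.65.

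In all, limma called 6996 of 15268 genes, 3156 higher and 3840 lower in loaded Nb3 alloy, and 3475 of them had an absolute log2 fold change of at least 1. The direction that prevailed depended on scaling. Total reads gave 2265 higher and 4679 lower, with the median of all genes at -0.17, and quantile normalization 3573 higher and 3337 lower, with that median at 0.06. Camera called 23 of 40 lists, 17 higher and 6 lower, fry called 23, and with an estimated correlation 0 were called by camera (smallest adjusted p = 0.265).

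**Figure D2:**
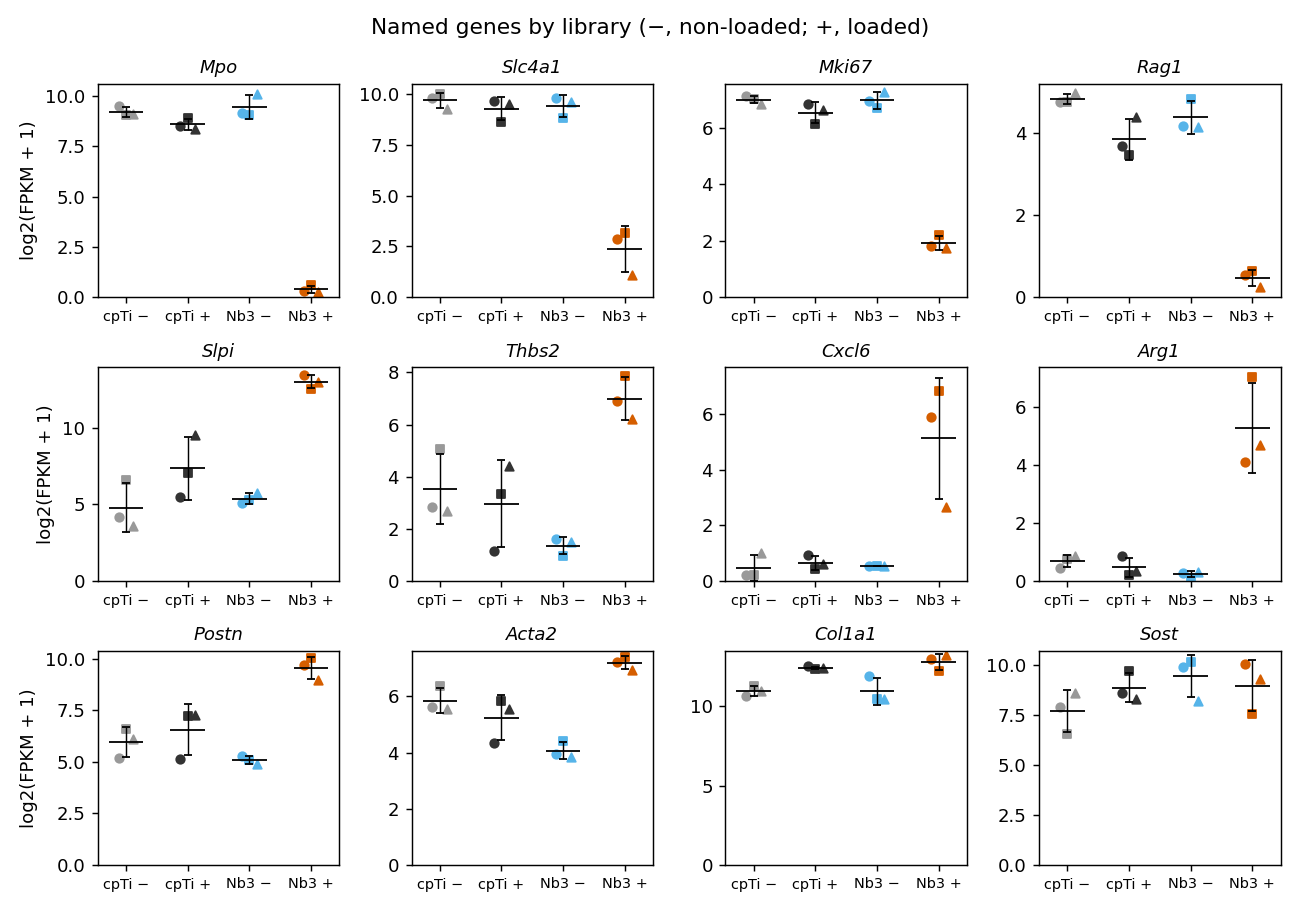
FPKM of 12 genes as log2(FPKM + 1), 1 point per library, with circles, squares and triangles for replicates 1, 2 and 3, lines at the mean and bars for the SD (n = 3). Mpo, Slc4a1, Mki67 and Rag1 lie low and Slpi, Thbs2, Cxcl6 and Arg1 lie high in loaded Nb3 alloy, while Sost overlaps between groups.

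**Figure D3:**
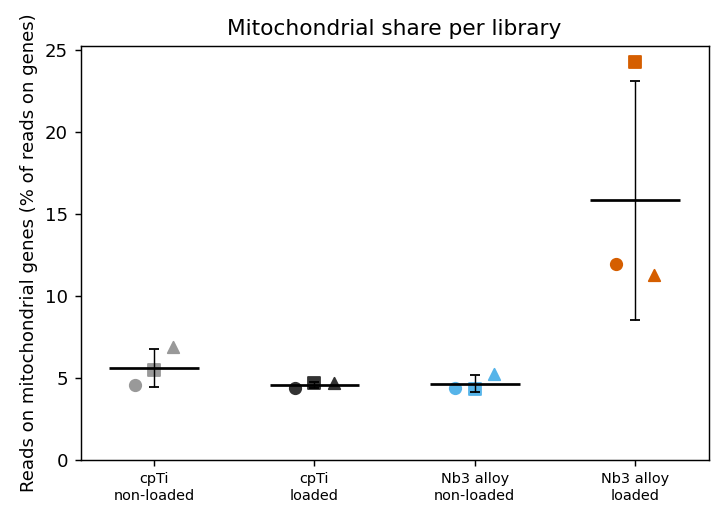
Reads on mitochondrial genes as a percent of reads on genes, 1 point per library, with circles, squares and triangles for replicates 1, 2 and 3, lines at the mean and bars for the SD (n = 3). Loaded Nb3-alloy libraries run from 11.3% to 24.3% and the other 9 from 4.31% to 6.86%.

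Loading beside cpTi left nearly all genes short of the threshold. Osteoblast genes had a median log2 difference of 0.92, with 20 of 23 above 0. Col1a1 stood at 5468 ± 302 FPKM in loaded and 2024 ± 476 FPKM in non-loaded samples (log2 difference 1.46, SE 0.42, adjusted p = 0.602), Sp7, an osteoblast transcription factor, at 33.6 ± 11.2 and 15.2 ± 1.44 FPKM (1.05, adjusted p = 0.728) and Dmp1, an osteocyte matrix gene, at 267 ± 66.2 and 126 ± 23.3 FPKM (1.06, adjusted p = 0.733). None of the 12 panel genes was called. Spp1 turned to -0.07 without loaded replicate 2 and to -0.25 without non-loaded replicate 1. The others were Sost (1.17), Alpl (1.11), Bglap (0.89), Acp5 (0.82), Tnfsf11 (0.66), Tnfrsf11b (0.60), Ctsk (0.45), Runx2 (0.39) and Spp1 (0.15), with adjusted p between 0.747 and 0.963.

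By limma 0 of the 23 osteoblast genes were called over all genes and 5 adjusted over the list alone, and camera placed the list higher (adjusted p = 1.43e-09, adjusted p = 0.622 with an estimated correlation, adjusted p = 0.624 by fry). The osteocyte list had a median of 0.92 (adjusted p = 2.67e-06, adjusted p = 0.622 with an estimated correlation), with 0 genes called either way. Collagens had a median of 0.48 with 3 genes adjusted over the list alone (adjusted p = 6.34e-07, adjusted p = 0.622 with an estimated correlation), and osteoclast genes a median of 0.48 (adjusted p = 4.04e-05, adjusted p = 0.622 with an estimated correlation). Lower by camera were cell cycle (median -0.32, adjusted p = 2.67e-06), erythroid (-0.38, adjusted p = 0.000373), B lineage (-0.52, adjusted p = 0.000616) and neutrophil genes (-0.46, adjusted p = 0.00135), each with adjusted p = 0.626 with an estimated correlation. The erythroid list lost its call without loaded replicate 2 (adjusted p = 0.278). Camera called 18 of 40 lists, 14 higher and 4 lower, while 0 were called with an estimated correlation and 0 by fry.

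The count by limma was 1 of 15268 genes, with 1062 at an unadjusted p under 0.05 where chance alone gives 763.4. That gene, Gm25820 (ENSRNOG00000055118), a small Cajal body RNA, stood at 0.820 ± 0.227 FPKM in loaded and 5.50 ± 0.297 FPKM in non-loaded samples and fell by 1.84 (SE 0.20, adjusted p = 0.0279). Its symbol, Gm with a number, was counted as a placeholder, a reading of the naming rule that was settled after its value was seen. No other gene was called, so the 3 genes with the smallest p are given. The other 2 carry no symbol and were not called. They lie on chromosome 4, 162002326 to 162009704 (-0.98, adjusted p = 0.0539) and on chromosome 8, 70580141 to 70605027 (-1.86, adjusted p = 0.0706). A polyA library measures a short RNA such as Gm25820 poorly, and limma-voom, a replicate block, a pseudocount of 0.1 and the fit of these groups alone each gave 0 genes. The count was 4 without non-loaded replicate 1, 1 without loaded replicate 3, and 0 without loaded replicate 1, loaded replicate 2, non-loaded replicate 2 or non-loaded replicate 3. Gm25820 itself was not called without any 1 of these 6 libraries (-1.90 to -1.74).

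Material under loading was compared on the same 3 loaded Nb3-alloy libraries as loading beside the alloy, so these comparisons are not independent. Mpo stood at 0.328 ± 0.169 FPKM beside loaded Nb3 alloy and 392 ± 75.9 FPKM beside loaded cpTi (-8.20, SE 0.27, adjusted p = 3.08e-08), Rhag at 0.494 ± 0.224 and 77.7 ± 25.8 FPKM, and Mki67 at 2.81 ± 0.697 and 93.5 ± 23.0 FPKM. Slpi stood at 8354 ± 2446 and 305 ± 380 FPKM (5.64, SE 0.94, adjusted p = 0.00126). Fdcsp averaged 138 ± 167 FPKM beside the alloy and was listed at 0 in the 3 loaded cpTi libraries. It was called, but not by limma-voom (8.70) or with only these groups in the fit (5.44).

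Of the marrow lists, 21 of 21 erythroid genes were lower (21 adjusted over the list alone, median -5.21, adjusted p = 1.3e-21), as were 28 of 28 cell cycle genes (28, median -2.93, adjusted p = 1.48e-25), 18 of 25 neutrophil genes (20, median -4.59, adjusted p = 1.45e-12) and 11 of 11 mast cell genes (11, median -2.59, adjusted p = 8.53e-07), each with adjusted p = 0.286 with an estimated correlation. The neutrophil genes Elane, RatNP-3b, Np4, Defa5 and Ctsg differed by -7.43, -7.36, -7.27, -7.26 and -7.13, and the red cell genes Car1 and Slc4a1 by -7.52 and -6.90. Of 23 B lineage genes 18 were lower and 1 higher (19 and 2 adjusted over the list alone, adjusted p = 6.7e-06, adjusted p = 0.301 with an estimated correlation), and of 12 megakaryocyte genes 9 were lower (9 lower and 1 higher adjusted over the list alone, adjusted p = 6.88e-06, adjusted p = 0.299 with an estimated correlation). Higher beside the alloy were 19 of 27 collagen and matrix genes (22 adjusted over the list alone, median 1.22, adjusted p = 2.04e-08, adjusted p = 0.299 with an estimated correlation), 12 of 16 smooth muscle genes (15, adjusted p = 8.53e-07, adjusted p = 0.286 with an estimated correlation), 11 of 16 Schwann cell genes (14, adjusted p = 6.7e-06, adjusted p = 0.301 with an estimated correlation) and 15 of 22 cytokine genes (16, adjusted p = 2.4e-06, adjusted p = 0.301 with an estimated correlation). Examples are Fmod (3.35), Postn (3.01), Tagln (2.22), Nos3 (2.45), Cxcl6 (4.47), the neutrophil chemokine gene Cxcl2 (4.15) and Cxcl1 (2.88), and outside these lists Cxcl13 (4.92), Arg1 (4.79), Matn4 (4.67) and Acod1 (4.41). Matn4 lost its call without loaded cpTi replicate 1 (3.70), and Cxcl2 (8.17) and Cxcl6 (5.83) lost theirs by limma-voom. Mitochondrial reads were 15.8 ± 7.30% beside loaded alloy and 4.57 ± 0.168% beside loaded cpTi.

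The osteoblast list was not called in this comparison, with 4 of 23 genes higher (1 adjusted over the list alone, median 0.36, adjusted p = 0.0902), nor was the osteocyte list, with 1 of 14 (1, adjusted p = 0.129). Both were called without loaded Nb3-alloy replicate 2 (adjusted p = 0.000146 and 0.00625) and without loaded cpTi replicate 2 (adjusted p = 0.0292 and 0.0484). Of the panel, Spp1 (1.15, adjusted p = 0.0424) and Tnfsf11 (1.12, adjusted p = 0.0425) passed and the other 10 did not. Without loaded Nb3-alloy replicate 2, Ctsk (1.83), Acp5 (1.56), Alpl (1.38) and Dmp1 (1.37) were called as well. Spp1 lost its call without loaded Nb3-alloy replicate 1 (1.19) or 3 (0.93) and without loaded cpTi replicate 1 (0.97) or 3 (1.12). Tnfsf11 lost its call without loaded Nb3-alloy replicate 1 (0.78) or 2 (1.13) and without loaded cpTi replicate 1 (0.96) or 2 (1.04). Both also lost it by total-read scaling (0.98 and 0.97), without a filter and with a replicate block, Spp1 by quantile normalization (0.71), and Tnfsf11 with a pseudocount of 0.1 (1.32) and with only these groups in the fit. Limma called 5123 genes, 2239 higher and 2884 lower, of which 2275 had an absolute log2 fold change of at least 1, and camera called 20 lists, 14 higher and 6 lower (0 with an estimated correlation, smallest adjusted p = 0.286, and 20 by fry). Scaling by total reads gave 1354 higher and 3679 lower, and quantile normalization turned the majority, with 2727 higher and 2456 lower.

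Without loading, no gene separated the materials by limma. The count was 0 of 15268, with 470 at an unadjusted p under 0.05 where chance alone gives 763.4, and limma-voom also gave 0. The smallest p belonged to Cnn1, a calponin of smooth muscle, at 0.260 ± 0.177 FPKM beside Nb3 alloy and 2.74 ± 0.466 FPKM beside cpTi (log2 difference -1.57, SE 0.22, adjusted p = 0.247), to Gm25820 (-1.32) and to a copy of RNaseP_nuc (-1.61), also at adjusted p = 0.247. The panel ranged from Sost at 1.73 (SE 0.74) and Dmp1 at 1.14 to Ctsk at -0.14, each at an adjusted p of 1. Without non-loaded cpTi replicate 1 the count was 4, and without a filter it was 1.

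Several lists differed by camera in these non-loaded samples. Smooth muscle genes had a median of -0.61 with 0 called over all genes and 5 lower adjusted over the list alone (adjusted p = 8.14e-11, adjusted p = 0.493 with an estimated correlation). Schwann cell genes had a median of -0.82 (adjusted p = 8.25e-09) with 1 lower adjusted over the list alone, megakaryocyte genes 0.68 (adjusted p = 5.31e-09) and osteocyte genes 0.81 (adjusted p = 8.99e-08) with 1 higher each, and all 3 had adjusted p = 0.509 with an estimated correlation. Camera called 14 lists, 7 higher and 7 lower, while 0 were called with an estimated correlation and 0 by fry (smallest adjusted p = 0.419). Without non-loaded cpTi replicate 2 camera called 9.

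**Figure D4:**
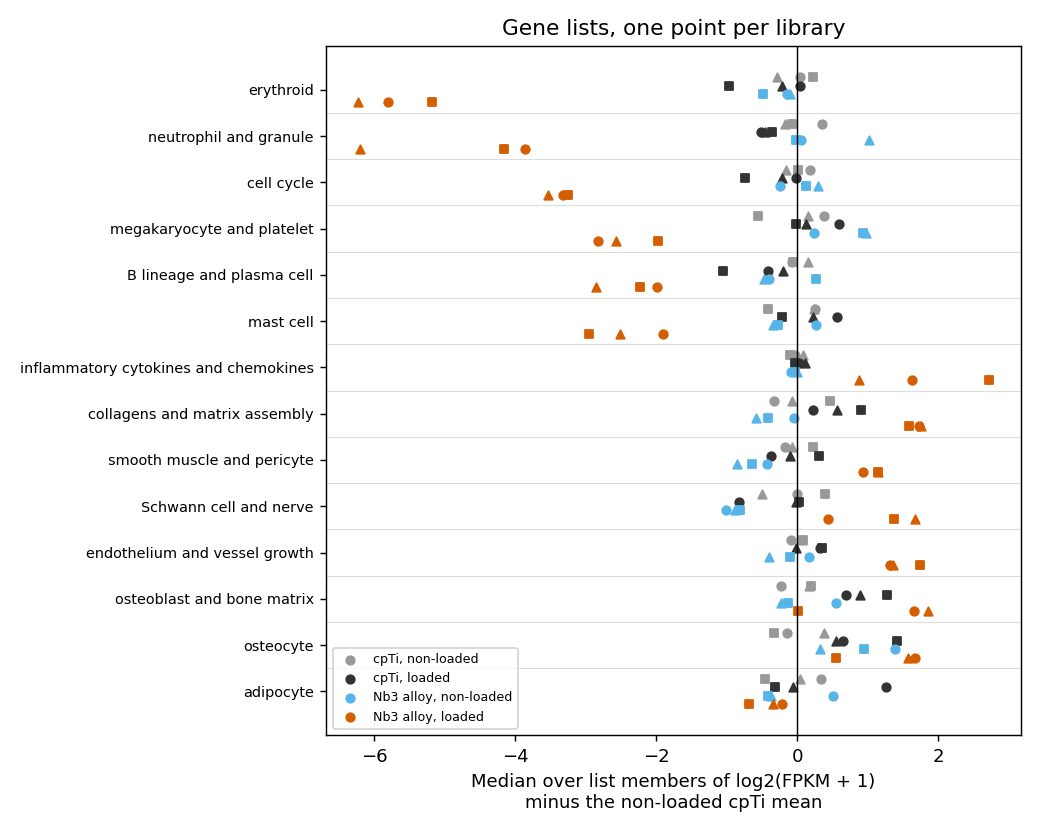
Median over list members of log2(FPKM + 1) minus the non-loaded cpTi mean, for 14 gene lists, 1 point per library, coloured by group, with circles, squares and triangles for replicates 1, 2 and 3. Erythroid, neutrophil and cell cycle lists lie below 0 and collagen, smooth muscle and Schwann cell lists above 0 in the loaded Nb3-alloy libraries.

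The interaction asked whether loading acted differently beside the alloy than beside titanium. It was called for 3089 genes, 1285 with a higher and 1804 with a lower loading effect beside Nb3 alloy. Mpo went from 738 ± 329 to 0.328 ± 0.169 FPKM under loading beside the alloy and from 600 ± 109 to 392 ± 75.9 FPKM beside cpTi, an interaction of -8.43 (SE 0.38, adjusted p = 9.89e-07). Thbs2 (6.18), the matrix gene Mfap4 (5.92), Cxcl13 (5.33) and Arg1 (5.25) had a higher loading effect beside the alloy, although by limma-voom Cxcl13 (5.62) and Arg1 (8.49) were not called. All 28 cell cycle genes (28 adjusted over the list alone, median -2.97), 20 of 21 erythroid (21, -4.84) and 18 of 25 neutrophil genes (18, -4.92) had a lower one, and 16 of 27 collagen genes (19, 1.71), 14 of 16 Schwann cell (15, 2.32) and 10 of 16 smooth muscle genes (12, 2.06) a higher one. These 6 lists had camera adjusted p of 8.73e-28, 2.87e-22, 2.38e-14, 1.89e-09, 5.33e-08 and 6.47e-09, each with adjusted p = 0.258 with an estimated correlation. The osteoblast list, with 1 of 23 genes called (1 adjusted over the list alone), had a median of 0.17 (adjusted p = 0.234), and the osteocyte list, with 0 called and 0 adjusted over the list alone, a median of -0.45 (adjusted p = 0.805). The osteoblast list was called higher without loaded Nb3-alloy replicate 2 (median 0.67, adjusted p = 0.00364) and was also called without non-loaded Nb3-alloy replicate 1 (adjusted p = 0.0442). Camera called 18 lists, 12 higher and 6 lower (0 with an estimated correlation, 17 by fry). The gene count was 1986 without loaded cpTi replicate 1 and 2018 without non-loaded Nb3-alloy replicate 3, and scaling by total reads gave 845 higher and 2380 lower, against 1397 and 1638 by quantile normalization.

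Averaged over materials, loading raised Slpi (5.09, SE 0.66), Matn4 (3.72), Cxcl13 (3.27), the macrophage elastase gene Mmp12 (2.74) and Fdcsp (2.68), and lowered RatNP-3b (-5.13), Defa5 (-5.10), Np4 (-4.98), Mpo (-4.83) and Elane (-4.13). Mmp12 lost its call (2.15 to 2.79) without any 1 library except loaded Nb3-alloy replicate 1, loaded cpTi replicate 3 and non-loaded cpTi replicate 3. Fdcsp lost its call (1.95 to 2.72) without any 1 library except loaded Nb3-alloy replicate 1. Osteoblast genes rose in 9 of 23 cases (9 adjusted over the list alone, median 0.89, adjusted p = 8.75e-06, adjusted p = 0.331 with an estimated correlation), including Postn (2.53), Col1a1 (1.65), Sparc (1.61) and Col5a2 (1.54). Limma called 5713 genes, 2442 higher and 3271 lower, and 1291 of them had an absolute log2 fold change of at least 1. Total-read scaling gave 1731 higher and 3845 lower, and quantile normalization 2861 and 2863. Averaged over loading, Slpi (3.11), the microRNA gene Mirlet7d (2.38), Cxcl13 (2.26), Cxcl6 (2.26) and Arg1 (2.17) were higher and Mpo (-3.99), Car1 (-3.65), Np4 (-3.63), Defa5 (-3.59) and RatNP-3b (-3.59) lower beside the alloy. Mirlet7d, at 0 to 18.8 FPKM in the 12 libraries, is another short RNA that a polyA library measures poorly. Arg1 was not called by limma-voom (2.47). Cxcl13 lost its call (1.92 to 2.46) without any 1 library except loaded Nb3-alloy replicate 3, loaded cpTi replicate 2 and non-loaded cpTi replicate 3. Cxcl6 lost its call (2.07 to 2.33) without any 1 library except replicates 2 and 3 of loaded Nb3 alloy, 2 of loaded cpTi, and 3 of each non-loaded group. That comparison called 1875 genes, 513 higher and 1362 lower, of which 527 had an absolute log2 fold change of at least 1. The split was 289 higher and 1782 lower by total reads and 818 and 1256 by quantile normalization. The count was 1095 without loaded cpTi replicate 1, 1093 without loaded cpTi replicate 3 and 1082 without non-loaded cpTi replicate 1. Camera called 27 lists for averaged loading (21 higher, 6 lower) and 24 for averaged material (18 higher, 6 lower), with 0 and 0 by an estimated correlation (smallest adjusted p 0.301 and 0.241) and 23 and 13 by fry. Both averages contain the loaded Nb3-alloy group. Loading beside cpTi alone called 1 gene, and material without loading called 0. An averaged value therefore does not by itself show an effect in both materials or in both loading states. Mpo, lower beside the alloy on average, stood at 738 FPKM beside non-loaded Nb3 alloy and 600 FPKM beside non-loaded cpTi.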

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

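Of the tests in this part, those of a lower marrow share, of the authors' scaling and of a shared batch were chosen only after the result was seen, while the neutrophil and cytokine tests and the splits were fixed before.

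The loading effect differed between the materials for 3089 genes by limma's interaction test, which is what singled out the following results. The genes whose loading effect was higher beside Nb3 alloy by the largest amount under the naming rule were Matn4 (6.47; 5.51 and not called without loaded cpTi replicate 1, and 6.89 and not called by limma-voom), Thbs2 (6.18), Mfap4 (5.92), Cxcl13 (5.33) and Arg1 (5.25), and those where it was lower were Mpo (-8.43), Elane (-7.80), Car1 (-7.74), RatNP-3b (-7.54) and Ctsg (-7.39). Of 100 splits of the 12 libraries, 5 gave as many genes as the real 3089, so chance is not excluded by this measure. The highest other split gave 5572, which points to a structure of the samples: all 4 of the other splits as large kept the 3 loaded Nb3-alloy libraries together, and the highest among splits that parted them gave 0. A split that keeps these libraries together also keeps their loading effect, so this share of splits cannot decide on chance.

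The first pattern is that blood-forming and cell cycle genes fell while stromal and matrix genes rose in loaded Nb3 alloy. A lower share of marrow cells alone might raise the markers of all other cell types alike. The gap between the highest and lowest of 7 such list medians was at least 1.797 in each loaded library. In the non-loaded ones it was at most 0.901. Without the adipocyte list, whose cells also live in marrow, the gap was 0.826 in 1 loaded library. The log2(FPKM + 1) scale also understates changes of low genes, so lists need not rise alike. A lower marrow share alone is therefore not excluded. The authors' scaling multiplies all genes of a library alike and so cannot produce the 7.82 by which collagen and erythroid medians moved apart, against an SD of 0.630 within groups. The labels name no batch and no dates. A batch holding only these 3 libraries would coincide with their group, and the first principal component (59.1% of variance) would separate them under a batch and under a response alike, so it decides nothing. Open candidate explanations are a lower marrow share, alone or with a change in the stromal cells, and a difference in what bone was collected. A response to loading beside this alloy is open as well.

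The second pattern is that cytokine and chemokine genes rose while granule genes fell. A gain of mature neutrophils in place of precursors would raise mature genes. A list of 10 of these had a median of -1.65 (0 higher and 6 lower), beside -6.18 for 11 precursor genes. The mature median was -2.56, -0.22 and -2.26 in the 3 libraries. This argues against such a gain, although Cxcr2, Csf3r, Il1r2 and Fpr1 also belong to the neutrophil list that defined the pattern. The precursor genes Mpo, Elane, Prtn3, Ctsg, Ngp, Camp and Fcnb belong to that list as well. The low precursor median was therefore largely given by the pattern and is no separate evidence. Because mature genes fell less than precursor genes, a shift of the remaining neutrophils toward mature cells is not excluded. A lower marrow share might unmask cytokine genes made by other cells. Their median exceeded that of 116 non-marrow marker genes by 0.863 (2.06 against 1.197, one-sided permutation p = 0.00383 over genes, 100000 permutations, genes not being independent), but the difference was 0.505, 1.796 and -0.444 in the 3 libraries, so it cannot be told apart from unmasking. That all 3 libraries should agree was required only after these values were seen, and inflammation of the tissue stays open as well.

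For the simple comparisons, 3 libraries against 3 make 10 splits, which are too few for a share under 0.05. Genes called by the real split and by the highest other split were 6996 and 0 for loading beside Nb3 alloy (1 of 10 splits as large), 1 and 2 beside cpTi (2 of 10), 5123 and 0 for material under loading (1 of 10) and 0 and 0 without loading (10 of 10). Lists called were 23 and 24 (2 of 10), 18 and 22 (2 of 10), 20 and 26 (3 of 10) and 14 and 14 (2 of 10). For averaged loading the counts were 5713 genes against 5076 (1 of 100) and 27 lists against 31 (4 of 100). The gene count follows the loaded Nb3-alloy group, since only 5 other splits kept its 3 libraries together and the highest that parted them gave 1, so the share of splits does not exclude chance apart from that group. For averaged material chance was not excluded, with 1875 genes against 3956 (8 of 100, where all 7 others kept the 3 loaded Nb3-alloy libraries together and the highest that parted them gave 3) and 24 lists against 27 (6 of 100), nor for the interaction's lists, 18 against 29 (54 of 100). Since other splits called about as many lists as the real ones, a count of lists called by camera at the preset correlation carries little weight here.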

How the results depend on the processing

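Total-read scaling, nuclear-read scaling and quantile normalization were chosen only after the results were seen. Over all alternatives the values of named genes kept direction and side of the threshold in 12763 cases, lost the call in 826, gained one in 14, turned direction without a call in 35 and turned a called direction in 0. The count model was not run because the design set it aside for a file of FPKM, but recomputed size factors and limma-voom used the whole reads. The non-robust setting does not apply to the list test. Under total-read scaling the median of all genes moved to -0.17 for loading beside Nb3 alloy, -0.15 for material under loading, -0.18 for the interaction and -0.09 for averaged loading. The higher share of calls then fell from 45.1% to 32.6%, from 43.7% to 26.9%, from 41.6% to 26.2% and from 42.7% to 31.0%, while for averaged material it went from 27.4% to 14.0%. Quantile normalization moved these shares the opposite way, to 51.7%, 52.6%, 46.0%, 49.98% and 39.4%. Depth limits low genes: 1 read was worth 0.0554 to 0.0744 FPKM in a gene of 1 kb.

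With an absolute log2 fold change of at least 1 the counts were 3475 for loading beside Nb3 alloy, 2275 for material under loading, 1291 for averaged loading and 527 for averaged material. With that fold and an unadjusted p under 0.05 they were 3589, 2449, 1347 and 619, and 152 for loading beside cpTi and 127 for material without loading, because the adjustment was dropped. For loading beside cpTi the count was 2 without a filter, 3 by quantile normalization, and 0 with the filter on CPM, with a pseudocount of 0.1, by limma-voom and with only the groups compared in the fit. For material without loading it was 1 without a filter. The cause was not tested in these cases. With a correlation estimated per list, 0 lists were called in each of the 7 comparisons, because that test allows for the correlation among members. By fry 0 were called for loading beside cpTi, 0 for material without loading and 13 for averaged material.

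Leaving out 1 library at a time gave 5599 to 6948 genes for loading beside Nb3 alloy, 0 to 4 beside cpTi, 3429 to 4838 for material under loading, 0 to 4 without loading, 1986 to 3159 for the interaction, 4544 to 6002 for averaged loading and 1082 to 2057 for averaged material. The cause was not tested. The lists called ranged from 9 to 18 for material without loading, the lowest without non-loaded cpTi replicate 2.

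The replicate numbers gave no sign of pairing the samples. Of 18 pairs of libraries with the same number 1 correlated above 0.1 in their deviations from the group means (range -0.252 to 0.115). By mean correlation 0 libraries were closest to their own number. With 3 libraries per group this check is weak. The labels do not say whether samples share an animal, so pairing stays unknown. With the replicate number as a block the counts were 6568 for loading beside Nb3 alloy, 0 beside cpTi, 4591 for material under loading, 0 without loading, 2608 for the interaction, 5194 for averaged loading and 1482 for averaged material.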

Other observations

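Of the tests in this part, those of mitochondria-rich cells and of sequencing depth were chosen only after the result was seen, and that of RNA length was fixed before.

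Under loading beside Nb3 alloy, 11 of 21 lysosome genes rose (12 adjusted over the list alone, median 0.54, adjusted p = 0.0001, adjusted p = 0.265 with an estimated correlation), with the protease gene Ctsl at 1.89 and the lysosomal hydrolase gene Hexa at 0.92. Of 19 T and NK cell genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0297, adjusted p = 0.626 with an estimated correlation): Icos and Cd2 rose by 1.94 and 2.40, while Nkg7, which myeloid cells also express, fell by 5.25. Of 12 class II genes 4 rose (4 adjusted over the list alone, adjusted p = 0.0388, adjusted p = 0.626 with an estimated correlation), with RT1-Db1 at 1.60. Of 14 skeletal muscle genes 6 rose and 1 fell (8 and 1 adjusted over the list alone, median 2.15, adjusted p = 0.0329, adjusted p = 0.664 with an estimated correlation, 0.257 by fry). The contractile genes Myl1 (3.58, SE 1.13) and Tnnt3 (2.55, SE 0.82) rose, and both lost their call without loaded replicate 1 (3.43 and 2.57), without loaded replicate 2 (2.18 and 1.45) and without non-loaded replicate 3 (3.55 and 2.51), Myl1 also without non-loaded replicate 1 (3.52), and Tnnt3 without non-loaded replicate 2 (2.38). By limma-voom (6.14 and 3.01) and with only these groups in the fit both were not called either. The T and NK cell, class II and skeletal muscle lists lost their calls without loaded replicate 1 (adjusted p = 0.13, 0.116 and 0.073), without loaded replicate 2 (0.113, 0.178 and 0.159) and without non-loaded replicate 1 (0.0723, 0.0723 and 0.0538). Of 19 marrow stroma genes 7 rose and 3 fell (7 and 3 adjusted over the list alone) and the list was called only without non-loaded replicate 1 (adjusted p = 0.0472 against 0.0933), with Prrx1 at 1.73 and the niche chemokine gene Cxcl12 at -1.74, from 362 ± 42.0 to 109 ± 22.5 FPKM. Of 17 adipocyte genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, median -0.35, adjusted p = 0.741).

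Stress lists were not called in that comparison over all 12 libraries. Of 21 oxidative stress genes 6 rose and 5 fell (6 and 5 adjusted over the list alone, adjusted p = 0.759), among them the glutathione synthesis gene Gclm (-2.57) and the catalase gene Cat (-1.61), both of which fell. Of 21 heat shock and unfolded protein genes 5 rose and 2 fell (5 and 2, adjusted p = 0.297), with Hspb1 at 2.86 and Asns at -2.45. Of 21 hypoxia and glycolysis genes 5 rose and 1 fell (5 and 1, adjusted p = 0.308), with Hif1a at 1.63 and Vegfa at 1.23. Of 22 interferon genes 2 rose and 4 fell (0 and 1 adjusted over the list alone, adjusted p = 0.741), with Rsad2 at -4.93. Of 28 integrin and focal adhesion genes 12 rose and 6 fell (12 and 6, adjusted p = 0.0933, and 0.0406 without non-loaded replicate 1), with Lamb1 at 2.37. Of 29 ribosomal protein genes 0 were called by limma (0 adjusted over the list alone, median 0.16, adjusted p = 0.157, and 0.00374 without non-loaded replicate 2). The remaining lists were small: cartilage had 4 higher and 1 lower of 12 (5 and 1, adjusted p = 0.126, and 0.0233 without loaded replicate 2), oral epithelium 1 and 2 of 6 (2 and 2, adjusted p = 0.95), gland 1 and 0 of 5 (1 and 0, adjusted p = 0.239) and enamel and dentin 2 and 0 of 5 (2 and 0, adjusted p = 0.0856).

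The third pattern is that all 13 mitochondrially encoded protein genes rose in loaded Nb3 alloy by 1.74 to 2.02 (median 1.91), while under loading beside cpTi their median was -0.22 and limma called 0. The size depends on scaling, with a median of 1.73 by total reads and 0.62 by quantile normalization, where 7 of 13 were called. Cells richer in mitochondria would, if nothing else changed, also raise nuclear genes of oxidative phosphorylation. The 26 of these had a median of 0.0838 (quartiles -0.17 and 0.38, adjusted p = 0.378). Of them 4 were higher and 2 lower (3 and 2 adjusted over the list alone), so the list did not rise as a whole. A loss of other cells that express these genes could offset a gain, so a changed mix of cells is not excluded. Depth does not account for it in 2 loaded libraries, whose nuclear reads were at most 5% above the highest other library. They still had at least 1.64 times the highest other mitochondrial share. That window was widened after a stricter one left 1 library, and loaded replicate 2, with the most reads, fell outside it. Fold change and length had a Spearman rho of -0.0173 across 15236 genes, which are not independent replicates. Long genes thus did not fall more than short ones across these genes. With 6996 of 15268 genes called, a changed mix of cells could offset such a fall, so loss of long RNA is not excluded. Handling apart from the other libraries, stress or damage of cells, or a loss of cytoplasmic RNA may each still apply.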
